A study of Zea mays with 2 samples.

How the data were processed

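The series holds RNA-seq of maize endosperm, the starch- and protein-storing tissue of the kernel, taken 15 days after pollination from the defective-kernel mutant dek10 and from wild type. RNA was extracted with Trizol, then cleaned and treated with DNase I on a column kit, and libraries followed standard Illumina procedures, per the labels' protocols. The series' design text speaks of triplicates, but each genotype has 1 sample with 1 column of values here. Whether that column is a single library, a pool or a mean of several is not given in the sources used here, and it is called a library below.

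The authors deposited FPKM values, fragment abundances scaled by transcript length and library size, for 53679 rows per library, per the file headers. The submitters' processing notes name Bowtie version 0.12.2 and the genome build B73 RefGen_v3. The quantification program, the gene annotation and any filter are not given in the sources used here. Each row is labelled with a chromosome, a start and an end, and the files do not pair these with gene names. Both files list the same rows in the same order, and rows were paired by that order. Of the 53679 rows, 11683 share their coordinates with another row, which leaves 47541 distinct positions. Starts are counted from 0 in the files, where the smallest start is 0, so 1 was added to every start printed here.

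Nuclear loci are therefore given by position in B73 RefGen_v3, and whether a position is exonic, intronic or untranslated was not analysed here. The gene table used for names describes Zm-B73-REFERENCE-NAM-5.0, another assembly, and no position was converted between assemblies. None of the 53438 rows on chromosomes 1 to 10 had both ends equal to a gene of that table. On the mitochondrial sequence, 26 of 69 rows had both ends equal to a gene once 1 was added to the start, against 0 without it, so the mitochondrial sequence was taken to be the same in both. Mitochondrial rows took a protein-coding gene's name where both ends were equal (26 rows) or where that gene was the only one within the row (15 rows). Of 28 gene lists fixed in advance, 26 need nuclear gene names and were not analysed here. The mitochondrial and plastid lists were taken by chromosome. The dek10 gene itself was not analysed here, so the labels have no check from its level.

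With 1 library per genotype there is no replicate error, and no p-value is given. The ratio was log2 of dek10 over wild type after adding a pseudocount of 1 FPKM to both, which understates the change of low loci. Folds of single loci and of sums are ratios of FPKM without the pseudocount. Loci with at least 1 FPKM in at least 1 library were considered, and a 2-fold ratio on the log2 scale was the size that counted. The main scale is the deposited one. Median-of-ratios scaling divides the dek10 values by the median ratio of considered loci above 0 in both libraries. The mitochondrial list's median was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. The bins are too wide to match the most abundant loci, so no such comparison is given for the clusters.

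These choices, most alternatives in scaling, pseudocount, filter and size of ratio, and the rule for named loci were fixed before the data were examined. The rule names the 5 loci with the highest mean, up to 4 members per list with the highest mean and, without gene names, at most 2 loci higher and 2 lower by log2 ratio among loci with a mean of at least 10 FPKM. Clusters of abundant loci were defined after the values were seen, by a rule that does not use the ratio. A cluster is 3 or more rows on chromosomes 1 to 10, each with a mean of at least 500 FPKM and a span of at least 200 bp, separated by gaps of at most 200 kb.

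The number of reads behind each value is unknown. Among loci with coordinates of their own and spans of 300 to 1000 bp, few positive values equalled that of another locus of the same span. These were 6 of 6592 in dek10 and 4 of 5714 in wild type, so no step of 1 read was found there. At shorter spans some dek10 values did repeat, such as 2356 FPKM at 2 loci of 99 bp and 21.9 FPKM at 3 loci of 157 bp. Whether these stand for equal read counts was not tested. Spans can include introns, and equal spans need not mean equal transcript lengths. No counting interval is given, and an exact 0 is reported only as listed at 0. The calculation was tested on simulated data for dek10 against wild type. Both simulated libraries were the wild-type values with small random noise, and loci at 0 stayed at 0 in both. Changed loci were drawn from those of at least 10 FPKM. The noise was not estimated from these data, so the counts below check the calculation and give no rate of false calls for the real libraries. Of 200 loci changed 4-fold, 200 passed the 2-fold size among 25750 loci, as did 5 unchanged loci. Of 200 changed 2.5-fold, 159 passed among 25833 loci, as did 8 unchanged loci. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.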

Results

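Endosperm transcript abundance was compared between 1 dek10 library and 1 wild-type library at 15 days after pollination. dek10 belongs to the defective kernel mutants of maize, and its gene is known to encode a pentatricopeptide repeat protein that acts on RNA editing in mitochondria. The comparison addresses how the endosperm transcriptome differs in the mutant. The FPKM values summed to 1140726 in dek10 and 1167393 in wild type. At 1 FPKM or more, 27525 rows were detected in dek10, 25275 in wild type and 23212 in both, while 9477 rows were listed at 0 in dek10 and 11741 in wild type. There are no replicates, so every difference below is between 2 libraries and has no replicate check.

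The most abundant transcripts took a much smaller part of the mutant library. Ranked within each library, so that the loci can differ, the 10 most abundant made up 14.8% of the summed FPKM in dek10 and 31.1% in wild type. The 50 most abundant made up 30.2% and 54.0%. Rows under 200 bp held 15.2% of the dek10 sum and 9.26% of the wild-type sum. With spans of at least 200 bp, the shares of the 10 most abundant were 14.5% and 34.3%. The highest mean belonged to a 723-bp locus on chromosome 7 at 18865424 to 18866146, with 15729 FPKM in dek10 and 83091 FPKM in wild type, a 5.28-fold lower value. It alone held 7.12% of the wild-type sum and 1.38% of the dek10 sum. A locus on chromosome 4 at 21334901 to 21335979, whose coordinates are shared by another row, had 10099 FPKM in dek10 and 36766 FPKM in wild type, 3.64-fold lower.

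The remaining loci among the 5 most abundant differed by less than 2-fold on the deposited scale, but not all of them after median-of-ratios scaling. A locus on chromosome 7 at 120233940 to 120236057 had 21792 FPKM in dek10 and 30268 FPKM in wild type. On chromosome 6 at 44541825 to 44542774 the values were 19328 FPKM and 28944 FPKM. After that scaling both passed the 2-fold size, with log2 ratios of -1.06 and -1.17. A 167-bp locus on chromosome 8 at 19496970 to 19497136 had 27162 FPKM in dek10 and 19336 FPKM in wild type, a log2 ratio of 0.49 that turned to -0.093 after the scaling.

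Clustered loci with a mean of at least 500 FPKM had lower FPKM in dek10. The rule for clusters found 5 groups holding 29 rows, 3 groups on chromosome 4 and 2 on chromosome 7. Of these 29 rows, 27 were at least 2-fold lower in dek10, 0 were 2-fold higher and 2 lay between, and after median-of-ratios scaling all 29 were at least 2-fold lower. Together the clusters held 35.0% of the wild-type sum and 9.31% of the dek10 sum, and their summed FPKM was 3.84-fold lower in dek10, or 5.76-fold lower after that scaling. The median log2 ratio of the 29 rows was -1.97, and that of the 116 rows of at least 500 FPKM and 200 bp outside the clusters was 0.44. With the minimum mean lowered to 250 FPKM, 5 of 7 clusters were at least 2-fold lower in sum and the other 2 had ratios of 1.69 and 3.82, dek10 over wild type, on the deposited scale. With gaps up to 500 kb as the only change, 5 of 5 clusters were at least 2-fold lower, but these were not the same 5. The chromosome 4 clusters starting at 5083079 and 5521259 merged, and 3 rows on chromosome 1 between 161790710 and 162097052 formed a cluster.

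On chromosome 4, the cluster at 5083079 to 5177135 held 11 rows, all at least 2-fold lower, and its sum was 27340 FPKM in dek10 against 104822 FPKM in wild type. The neighbouring cluster at 5521259 to 5561370 held 6 rows, all lower, with 16251 FPKM against 64449 FPKM. The third cluster, at 29951761 to 30091004, held 4 rows, all lower, with 11483 FPKM against 46275 FPKM. In sum these clusters were 3.83-fold, 3.97-fold and 4.03-fold lower. The lowest ratio among the clustered rows was at 5083079 to 5084155, with 27.5 FPKM in dek10 and 2942 FPKM in wild type, a log2 ratio of -6.69.

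On chromosome 7, the cluster at 18755936 to 18878182 held 5 rows with spans of 722 to 726 bp, all lower. Its sum was 23004 FPKM in dek10 and 127106 FPKM in wild type, 5.53-fold lower, and its log2 ratios lay between -2.80 and -2.40. In the cluster at 120206897 to 120236057 the rows differed from each other. The locus at 120206897 to 120208211 had 1956 FPKM in dek10 and 29079 FPKM in wild type, 14.9-fold lower, while the rows that share the coordinates 120233940 to 120236057 were 1.38-fold and 1.39-fold lower. Of the 29 clustered rows, 17 share coordinates with another row. How reads were divided among rows at one position or among near-identical neighbours is unknown, so single rows are less certain than the sums.

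**Figure D1:**
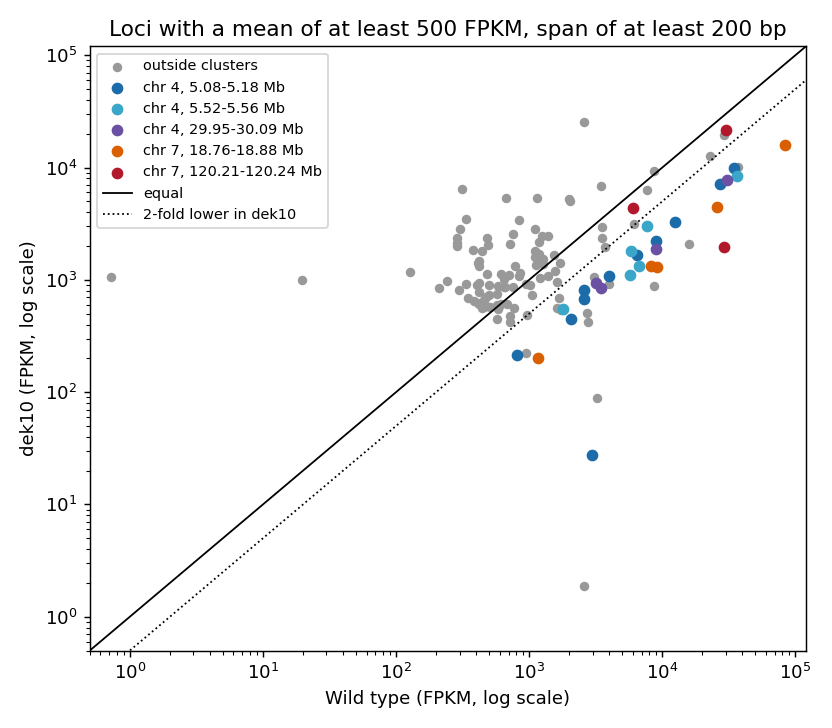
FPKM in wild type (horizontal, log scale) and in dek10 (vertical, log scale) of 136 loci with a mean of at least 500 FPKM and a span of at least 200 bp; each point is 1 row, coloured by cluster, and another 9 rows listed at 0 in 1 library are left out. The solid line marks equal values and the dotted line a 2-fold lower value in dek10, and 27 of the 29 clustered rows were at least 2-fold lower.

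Abundant loci outside the clusters went both ways, and their balance depended on the scaling. Of 116 such rows, 36 were at least 2-fold higher in dek10, 19 at least 2-fold lower and 61 between on the deposited scale, whereas 27 were higher and 29 lower after median-of-ratios scaling. They summed to 245463 FPKM in dek10 and 249950 FPKM in wild type. One region was chosen after its values were seen: on chromosome 1, 3 abundant rows between 161790710 and 162097052 summed to 3393 FPKM in dek10 and 27173 FPKM in wild type, 8.01-fold lower.

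Across the transcriptome, more loci had higher than lower FPKM in dek10 on the deposited scale, a balance that rests on the scale chosen between the libraries. Of 29588 considered loci, 6807 were at least 2-fold higher in dek10, 2008 at least 2-fold lower and 20773 between, and the median log2 ratio was 0.49. Median-of-ratios scaling, which shifts dek10 down by 0.58 on the log2 scale and centres the ratios by construction, left 2687 loci higher and 3109 lower with a median of 0.013. The share of higher loci among those passing the 2-fold size was 77.2% as deposited and 46.4% on the centred scale, so the latter is no evidence on the direction. Across genes, which are not independent replicates, the log2 values of the libraries had a Pearson r of 0.806, and Spearman's rho was 0.806.

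**Figure D2:**
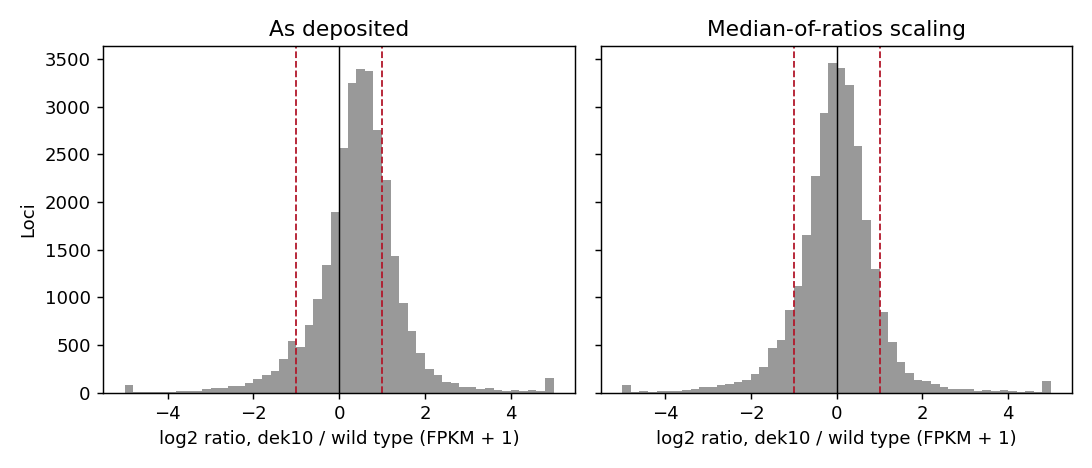
Number of loci (vertical) by log2 ratio of dek10 over wild type with 1 FPKM added (horizontal, values beyond 5 in either direction placed in the end bins), for 29588 considered loci, as deposited (left) and after median-of-ratios scaling (right). Dashed lines mark a 2-fold ratio and the solid line equal values; the median lies at 0.49 as deposited and at 0.013 after scaling.

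Chromosomes differed little from each other in this respect. The median log2 ratio ran from 0.46 on chromosome 3 to 0.51 on chromosome 8, and the share of loci at least 2-fold higher from 21.0% on chromosome 10 to 24.0% on chromosome 4. Among 10 equal bins of considered loci by mean FPKM, the most abundant bin had a median log2 ratio of 0.74, with 1030 of 2959 loci at least 2-fold higher and 188 lower. After median-of-ratios scaling its median was 0.17, with 438 loci higher and 293 lower, and the least abundant bin then had a median of 0.22, with 191 loci higher and 442 lower.

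The largest ratios in the set fixed by rule involved loci listed at 0 in 1 library, so no fold is given for them. An 83-bp locus on chromosome 1 at 168946851 to 168946933 had 6320 FPKM in dek10, and a locus on chromosome 7 at 148962512 to 148969683, which shares its coordinates with another row, had 5737 FPKM. Both were listed at 0 in wild type. A locus on chromosome 8 at 125066160 to 125069152, which also shares its coordinates, had 6491 FPKM in wild type, and an 81-bp locus on chromosome 4 at 32372571 to 32372651 had 5573 FPKM. Both were listed at 0 in dek10.

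The extremes were also taken, after the values were seen, among the 8167 loci with a mean of at least 10 FPKM, a span of at least 200 bp, coordinates of their own and values above 0 in both libraries. The locus on chromosome 6 at 14305953 to 14307860 had 732 FPKM in dek10 and 0.089 FPKM in wild type, and that on chromosome 1 at 270268846 to 270270776 had 1055 FPKM and 0.73 FPKM. In the other direction, the locus on chromosome 5 at 126701366 to 126701993 had 1.89 FPKM in dek10 and 2578 FPKM in wild type. The locus on chromosome 1 at 287133859 to 287135934 had 2.09 FPKM and 761 FPKM.

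Mitochondrion-encoded transcripts had low FPKM in both libraries and went both ways between them. How far the library preparation captured organelle RNA was not analysed here, so these values need not reflect organelle transcript levels. The 69 mitochondrial rows summed to 52.2 FPKM in dek10 and 34.7 FPKM in wild type. Most of that difference lay in 1 row, rps12, with 14.3 FPKM in dek10 and 0.915 FPKM in wild type. Of 19 considered rows, 4 were at least 2-fold higher in dek10, 1 at least 2-fold lower and 14 between on the scale with the pseudocount, which is as large as many of these values. By the plain FPKM ratio, 5 were at least 2-fold higher, 5 at least 2-fold lower, 7 between and 2 listed at 0 in 1 library. Their median log2 ratio was -0.050, at percentile 3.45 of random lists matched on mean FPKM and inside their central 95%, which ran from -0.091 to 0.74. After median-of-ratios scaling the median was -0.34. The 20 plastid rows did not exceed 0.377 FPKM, and 0 of them were considered.

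rps12, which encodes a protein of the small mitochondrial ribosomal subunit, had the highest mean of the mitochondrial rows. At 262384 to 262761 of the mitochondrial sequence, it had 14.3 FPKM in dek10 and 0.915 FPKM in wild type, a log2 ratio of 2.99. The next rows by mean lie at 266974 to 267231, 111497 to 115826 and 259447 to 260940 and took no gene name. Their log2 ratios were -0.68, -0.46 and -0.23. The position 111497 to 115826 is shared with other rows of lower mean, whose log2 ratios were 0.15 and 0.11.

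nad3 and cox2, whose transcripts are known editing targets in this mutant, were looked up after the values were seen. nad3, which encodes a subunit of respiratory complex I and lies at 262806 to 263162, next to rps12, had 1.30 FPKM in dek10 and 1.27 FPKM in wild type. The row containing cox2, a subunit of cytochrome c oxidase, at 541369 to 545055 had 1.09 FPKM and 0.830 FPKM. FPKM measures abundance and holds no information on editing. Among other respiratory genes looked up in the same way, nad4 had 0.907 FPKM in dek10 and 1.88 FPKM in wild type, atp6 had 0.645 FPKM and 1.32 FPKM, nad9 had 1.45 FPKM and 0.473 FPKM, and atp4 had 1.11 FPKM and 1.21 FPKM. The read depth behind these low values is unknown, and median-of-ratios scaling turned the log2 ratios of nad3 from 0.020 to -0.28 and of cox2 from 0.19 to -0.084.

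**Figure D3:**
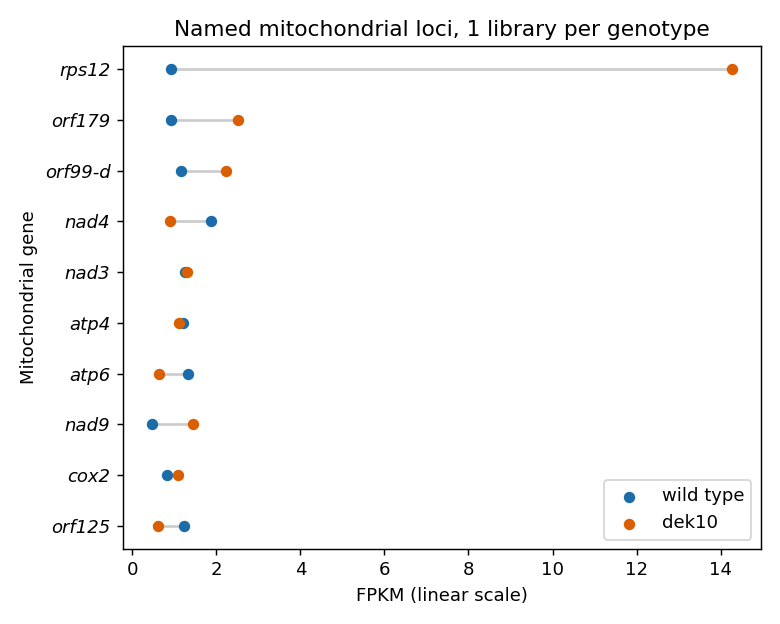
FPKM (horizontal, linear scale) of the considered mitochondrial rows that took a gene name (vertical), in 1 wild-type library (blue) and 1 dek10 library (orange), joined by a line per gene. rps12 stands at 14.3 FPKM in dek10 and 0.915 FPKM in wild type, while nad3 had 1.30 FPKM and 1.27 FPKM.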

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

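Settings on spans, on coordinates listed once, on the clusters and scaling without the clusters were chosen after seeing the data. Of 61 alternatives, 35 stayed within tolerance (a factor of 1.5 for counts, shares and ratios of sums, 0.1 for log2 medians, 0.05 for correlations) and 26 moved. None was scored as reversed, but most are counts, shares or correlations, which cannot reverse. The balance of higher over lower loci did turn round under several scalings given below. Several of the 35 are fixed by their setting and no check. These include 2 counts without a filter, the mitochondrial median without short spans, top-10 shares without organelles and cluster ratios under scaling. Loci at least 2-fold higher and lower in dek10, 6807 and 2008, became 2687 and 3109 under median-of-ratios scaling, 2724 and 3090 under the total without the 50 most abundant loci, and 2797 and 3039 under the upper quartile. The total without the clusters gave 3293 and 2753. Each scaling lowers the dek10 values by one constant, 0.58, 0.57, 0.55 and 0.45 on the log2 scale, and the balance follows its size; median of ratios centres the ratios by construction. A pseudocount of 5 gave 2758 and 678, a mean of at least 10 FPKM gave 2962 and 500, a 4-fold size gave 1136 and 559, and a 1.5-fold size gave 13206 and 3265, as stricter or looser settings must. The mitochondrial median log2 ratio, -0.050, was -0.34 under median-of-ratios scaling, -0.34 without the 50 most abundant loci, -0.33 under the upper quartile and -0.28 without the clusters. It was 0.035 without a filter, a sign change within tolerance, and no mitochondrial row had a mean of 10 FPKM. The correlation across genes, 0.806, was 0.698 at a pseudocount of 0.1, 0.889 without a filter, 0.552 at a mean of at least 10 FPKM and 0.886 without loci listed at 0; the cause was not tested. Rows detected at a floor of 5 FPKM were 16983 in dek10 and 14538 in wild type, and at 0.1 FPKM 40930 and 38218, just inside and just outside the tolerance. The ratio of summed FPKM in the clusters stayed between 0.174 and 0.306 in 10 alternatives. With both a mean of at least 250 FPKM and gaps up to 500 kb, 12 clusters formed and 5 were at least 2-fold lower in sum; of the 26 rows added, 3 were lower and 7 higher. The lower mean alone added 7 rows, 0 of them lower, and the wider gap alone added 3 rows, all lower. Those 3 are the chromosome 1 region singled out after its values were seen. Alternatives that need nuclear gene names, and the conversion to TPM planned for them, were not run. No paired analysis was possible because each genotype has 1 library, and none could be left out. Read depth is unknown, so no counting error could be given.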

Other observations

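The tests in this part were chosen after the results they measure had been seen. Outside the clusters, pairs of abundant rows went both ways. There were 12 pairs of abundant rows that shared coordinates or were separated by gaps of at most 200 kb. By summed FPKM, 5 were at least 2-fold higher in dek10, 3 at least 2-fold lower and 4 between. After median-of-ratios scaling 2 were higher and 5 lower. Several of these pairs are 2 rows at the same coordinates, so they need not be 2 neighbouring loci. The higher pair on chromosome 3 includes a row with 2398 FPKM in dek10 that was listed at 0 in wild type. On chromosome 1, the pair between 141745664 and 141750849 summed to 2381 FPKM in dek10 and 751 FPKM in wild type, and the rows at 197301249 to 197304338 to 7135 FPKM and 2750 FPKM. On chromosome 4, the rows at 21334901 to 21335979 summed to 11025 FPKM in dek10 and 40744 FPKM in wild type, 3.70-fold lower, and on chromosome 6 the pair between 39087615 and 39092487 was 3.01-fold lower. These pairs were singled out after their values were seen. Neighbouring loci with a mean of at least 5 FPKM and less than 20 kb apart had weakly related log2 ratios, with a Spearman rho of 0.177 across 2904 pairs, which are not independent replicates.

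The first pattern is the lower FPKM across the 5 clusters. Reads moved between copies within a cluster would leave its sum about equal, but the highest of the 5 ratios of sums, dek10 over wild type, was 0.430. The ratio over the clusters fell from 0.260 to 0.174 under median-of-ratios scaling. This is no test of scaling, because each scaling tried lowers all dek10 values by a constant. A constant shifts abundant rows about alike, though, so it does not give a gap between groups of them. The median log2 ratio was -1.97 for the clustered rows and 0.44 for other rows of at least 500 FPKM and 200 bp. Sequence differences between the parents at the arrays stay open, because low clusters lay on 2 chromosomes and a wholly different background, which the sources used here do not describe, could lower alignment at each of them. An effect of genotype or a difference in developmental stage also stays open and untested, since each genotype is 1 library.

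A related hypothesis is that the clusters are storage-protein arrays, because genes of zeins, the main storage proteins of maize endosperm, are known to lie in arrays on chromosomes 1, 4 and 7. Of the clustered rows, 0 lay on other chromosomes. The rows have no gene names and the idea came from these positions, so the clusters may hold other genes.

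The second pattern is the excess of loci higher in dek10 on the deposited scale. A candidate explanation is a few loci taking most of the wild-type total, which lowers the FPKM of the others there. After scaling by the total without the clusters, the median log2 ratio of loci outside them was 0.12, between the bounds of 0.1 and 0.25 set for the test, against 0.49 for considered loci on the deposited scale. With the 50 loci of highest mean left out of the total instead, the median of considered loci was 0.021. Leaving the clusters out of the total moved the median part of the way, and a wider set brought it inside the bound of 0.1. The answer depends on how many loci are left out. The totals are sums of FPKM, in which a short transcript weighs more than its share of reads. Transcript lengths and read counts are unknown, so these medians do not measure how far abundant loci lowered the others.

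The third pattern is the 42 loci with at least 1000 FPKM in 1 library and listed at 0 in the other. Length normalization of very short loci is a candidate source of the high values. It applies to both libraries alike, so it does not by itself give a 0, and read counts are unknown. Of the 42 loci, 33 spanned under 200 bp (78.6%), against 19 of 118 (16.1%) among loci of at least 1000 FPKM in 1 library and above 0 in both, a difference of 62.5 percentage points. Failed estimates at longer loci stay open for the remaining 9 loci, of which 7 share coordinates with another row. No biological explanation was tested.

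A last hypothesis was a linked block of differing sequence, such as a chromosome segment carried along with the mutation. Short rows, rows sharing coordinates and the surroundings of the clusters and of the chromosome 1 region were left out. Loci at least 1.5 log2 units from the median made up 9.27% of the 21168 remaining loci. The highest of 377 windows of 5 Mb was on chromosome 1 from 215 to 220 Mb, with 30.8% of 52 loci. Of 1000 shuffles of the loci, 9% gave a window at least as high, so this window does not stand out from chance. Windows needed only 20 loci, and those with few loci can reach a high share by chance. A block smaller than a window, or one with a lower share in a window of many loci, could therefore be missed. A block confined to the surroundings that were left out could not be found.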
